A study of Mus musculus with 4 samples.

How the data were processed

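Total RNA of 4 mouse hepatocarcinoma cell lines was profiled on the miRCURY LNA array of Exiqon, a glass array whose locked nucleic acid probes capture mature miRNAs, with 1 deposited sample per line. Per the labels, total RNA was isolated with TRIzol, labelled with the dye Hy3 in every sample, and read on a GenePix 4000B scanner, with grid alignment and extraction in GenePix Pro. Per the labels, the authors averaged replicate spots, took the miRNAs with an intensity of 50 or more in all samples, and divided each array by its median over them. The authors deposited 3 kinds of intensity, all linear: the foreground intensity of each spot, the same intensity after subtraction of a local background, and the normalized intensity of each probe. The local background, taken as the difference of the first 2, lay between 31 and 56 in every spot. The release of the probe annotation is not given in the sources used here.

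The array held 2448 probe positions with 4 spots each. Of these, 417 carried a mouse miRNA name, 77 were miRPlus probes (the maker's own sequences), 1595 were marked as not designed for mouse, 109 as obsolete and 80 were spike-control positions. The mean of the 4 background-subtracted spots equalled the deposited probe value exactly. The deposited normalized intensity equalled that mean divided by 1 factor per array, which was the median over the 65 mouse and miRPlus probes at 50 or more in all 4 arrays. The factor was 367 for H22, 403.75 for Hepa1-6, 396.25 for Hca-P and 324.5 for Hca-F. A level of 1 is therefore the median of these reference probes in that array. These values, recomputed from the spots, are the levels used here, and the error given with each is the SD over 4 spots. Where 2 probes carried 1 name (miR-298, miR-34c and miR-744), the brighter was kept, which left 414 miRNAs. The dimmer probes of miR-298 and miR-34c were under the detection minimum in every array (at most 35.5 and 13.5 units), while the ones kept reached 7859 and 150 units, so these values rest on 1 of 2 probes that disagree. The 2 probes of miR-744 also disagreed: the dimmer gave levels of 0.509 in H22 and 0.187 in Hca-P, against 0.418 and 0.595 from the one kept, and was under the detection minimum in Hepa1-6 and Hca-F, where the one kept gave 0.142 and 0.354.

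A miRNA with a background-subtracted intensity under 50 was treated as not measured in that array and set to 50 before scaling, so that a fold against it is a lower bound, written "at least". The floor corresponds to a level of 0.136 in H22, 0.124 in Hepa1-6, 0.126 in Hca-P and 0.154 in Hca-F. Each pair of lines was compared over the miRNAs at 50 or more in at least 1 of them, and a difference of 2-fold or more was counted. With 1 array per line no test of a pair of lines is possible, and the number of arrays limits the precision. Spots of 1 array are not replicates of a line, so no p-value was made from them. Lines with and without lymphatic metastasis were also compared with limma (lmFit and eBayes with an intensity trend, Benjamini-Hochberg adjustment, threshold 0.05), each line being 1 of 2 replicates of its class. Hca-P and Hca-F both derive from H22 per the labels, so the lines are not independent and the limma p-values measure only the spread between these arrays.

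The miRNAs named for a pair of lines followed a rule fixed before the data were examined. It took the 10 largest folds in each direction among those measured in both lines, 2-fold apart under the main scaling and after quantile normalization, and apart by more than 2 combined spot SDs. It then took up to 5 lower bounds in each direction, up to 10 miRNAs in each direction for the metastasis, graded and growth form comparisons, and the first listed and up to 3 further members of each fixed list. A few further members are named to complete a list. Fixed lists covered miRNA families and clusters, hepatocyte miRNAs, miRNAs of other cell types (leukocyte, erythroid, endothelial, mesenchymal, muscle and neuronal), the hypoxia miRNA miR-210, and miRNAs reported to promote or restrain metastasis. A list's median log2 fold over its measured members was placed among 10000 random lists of the same size matched on mean level, where at least 3 members were measured. That percentile describes these arrays only. Random lists are drawn as if members were independent, while members of a family or cluster may vary together. The percentile is therefore no p-value and may overstate how unusual a list is. Where measured members are bounds, the detection floor sets the median in part. The Sfmbt2 list counts 1 probe, for miR-466d-3p, whose name carries a suffix that the sources used here do not explain.

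The alternatives were quantile normalization, the 75th percentile of the mouse probes, no scaling, detection minimums of 30 and 100, normexp background correction with an offset of 50, the authors' normalized values, the median of spots, all capture probes, thresholds of 1.5-fold and 3-fold, and, for the lists, the brighter arm of each hairpin alone. The limma comparison was repeated without each line, without the trend, without the detection filter and on log2 of the value plus 50. The deposited design text names only Hepa1-6 and Hca-F, while samples of 4 lines were given, and all 4 were used. Probes marked as not designed for mouse, obsolete and miRPlus probes entered only the alternative with all capture probes and the checks in the closing section.

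The steps were tested on simulated data with known answers. For Hca-F over Hca-P, 20 of 414 miRNAs were given true folds of 3 or 6. They were drawn only from miRNAs with a simulated level of 100 units or more in every array. The shares called therefore do not cover miRNAs nearer the detection minimum. Of these 20, 95.2% of the 3-fold and 97.8% of the 6-fold differences were called, with 0.42 false calls on average over 100 simulations. For the limma comparison, 100% of 20 true 16-fold differences among 103 miRNAs were called, with 0.5 false calls on average over 20 simulations. In it every miRNA had the same spread and the arrays were independent. The largest limma difference in the data was smaller than 16-fold, a log2 of -3.16 for miR-697. Whether differences of the sizes reported here would be called was therefore not tested. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.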

Results

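The miRNA content of 4 mouse hepatocarcinoma lines that differ in their ability to spread to lymph nodes was measured on LNA capture arrays, 1 array per line. H22, grown in suspension, and Hepa1-6, an adherent line, have no lymphatic metastasis per the labels. Hca-P and Hca-F derive from H22, also grow in suspension, and have a lower and a higher lymphatic metastasis ability. With 1 array per line, none of the differences between 2 lines has a replicate check, and errors given as ± are SDs over 4 spots of that array. Levels are normalized intensities, with 1 as the median of the reference probes of an array. Of 414 mouse miRNAs, 87 were at or above the detection minimum in H22, 71 in Hepa1-6, 75 in Hca-P and 74 in Hca-F, and 103 in at least 1 line. The median over all mouse probes was 10.8 intensity units in H22, 3.50 in Hepa1-6, 11 in Hca-P and 7.5 in Hca-F, so most probes lay near the background. The brightest spike-control probe reached 27.2 units in any array, below the detection minimum of 50. miR-711 (30.2 ± 3.48 in H22), miR-709 (28.0 ± 3.70 in Hca-F) and miR-298 (24.2 ± 2.87 in Hca-F), chosen after the values were seen, were among the brightest, miR-298 by 1 of its 2 probes, the other being under the detection minimum in each line.

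The arrays were not independent measurements. Deviations of single spots from their probe mean correlated at r = 0.697 between H22 and Hepa1-6 and at r = 0.697 between Hca-P and Hca-F, over spots of 345 and 323 probes. The other 4 pairs of arrays gave 0.156 to 0.244. These correlations run across spots, which are not replicates. Over the 103 miRNAs, the log2 levels of Hca-F correlated most closely with those of Hepa1-6 (r = 0.916) and Hca-P (0.897), and at 0.769 with H22, the line it derives from per the labels. Hca-P correlated at 0.776 with H22 and 0.753 with Hepa1-6, and H22 at 0.783 with Hepa1-6. Values under the detection minimum were set to the floor for these correlations. Of the 103 miRNAs, 81 were measured in Hca-F or Hepa1-6, 85 in Hca-F or Hca-P and 95 in Hca-F or H22. The rest lay at the floor in both lines of the pair, which can raise r. How far this sets the order of the correlations was not tested. Comparisons of Hca-F with Hca-P and of H22 with Hepa1-6 lie within these pairs, and all others run across them.

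Hca-F was compared with Hca-P, lines of 1 origin with higher and lower lymphatic metastasis ability. let-7 miRNAs, a family known for tumour-suppressing activity against RAS and HMGA2, were lower in Hca-F. let-7a was at 0.475 ± 0.0670 in Hca-F and 5.15 ± 0.448 in Hca-P, 10.9-fold lower, and let-7d at 0.438 ± 0.0452 and 3.96 ± 0.403, 9.03-fold lower. let-7i was at least 3.71-fold lower in Hca-F. miR-23a (at least 3.92-fold) and miR-22 (at least 2.27-fold) were lower as well. Of 6 measured let-7 members, 3 were 2-fold or more lower in Hca-F and none higher. let-7b, let-7c and let-7e differed by less than 2-fold, with log2 folds of 0.18, -0.60 and 0.45. The let-7 median log2 fold of -1.25 lay at percentile 0.08 of random lists. It averages let-7c and the bound of let-7i, so the detection floor sets it in part: it was -1.61 with a minimum of 30 and -0.75 with 100, within -1.75 to -0.75 over the alternatives.

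The miR-17-92 cluster, a set of growth-promoting miRNAs induced by MYC, was also lower in Hca-F. Its 4 measured members had a median log2 fold of -1.05 (percentile 0.555; -1.55 to -0.40 in the alternatives), set in part by the bound of miR-18a. miR-17 was 2.34-fold lower (0.515 ± 0.0811 against 1.21 ± 0.0831), miR-18a at least 2.11-fold lower and miR-20a at 0.201 ± 0.105 against 0.408 ± 0.103, within 2 combined spot SDs. miR-19b, under the detection minimum in Hca-F, had a log2 fold of -0.07, a bound. miR-106b, of a paralogous cluster, was 2.19-fold lower (0.182 ± 0.0570 against 0.398 ± 0.0536), and miR-93 had a log2 fold of -0.23, a bound. miR-763 was 2.24-fold lower. In the other direction, miR-713 was 3.24-fold higher in Hca-F (0.565 ± 0.138 against 0.174 ± 0.0759), miR-340-5p 2.93-fold (0.503 ± 0.0491 against 0.172 ± 0.0169), miR-688 2.90-fold and miR-709 2.57-fold. miR-34a, a target of p53, was at 1.07 ± 0.126 in Hca-F and 0.515 ± 0.0570 in Hca-P, a log2 fold of 1.06. miR-490, miR-214 and miR-761 were at least 2.15-fold, 2.14-fold and 2.03-fold higher, the last 2 within 2 combined spot SDs. The Sfmbt2 cluster, a rodent-specific imprinted group of repeated miRNAs, had 3 of 5 measured members higher in Hca-F and a median log2 fold of 1.19 (percentile 99.4; 0.69 to 1.26 in the alternatives). Its higher members were miR-669a (log2 1.19), miR-669c (1.45) and the probe for miR-467a* and miR-467d* (1.29), the last 2 within 2 combined spot SDs. Taken spot by spot, since the spots of these arrays share deviations, the 3 log2 folds had SDs of 0.61, 0.63 and 0.15, which puts miR-669a within 2 SDs and the others beyond.

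In all, 31 of 85 miRNAs were 2-fold or more apart between Hca-F and Hca-P, 20 higher and 11 lower in Hca-F, and 20 of them by more than 2 combined spot SDs, or 26 by more than 2 SDs of the log2 fold taken spot by spot. The direction of that split depended on the scaling: it was 6 higher and 13 lower after quantile normalization, 6 and 15 without scaling, and 3 and 21 when all capture probes set the factor. The median over the 85 miRNAs was 0.45 on the log2 scale and 0.14, 0.16 and -0.05 under those scalings.

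**Figure D1:**
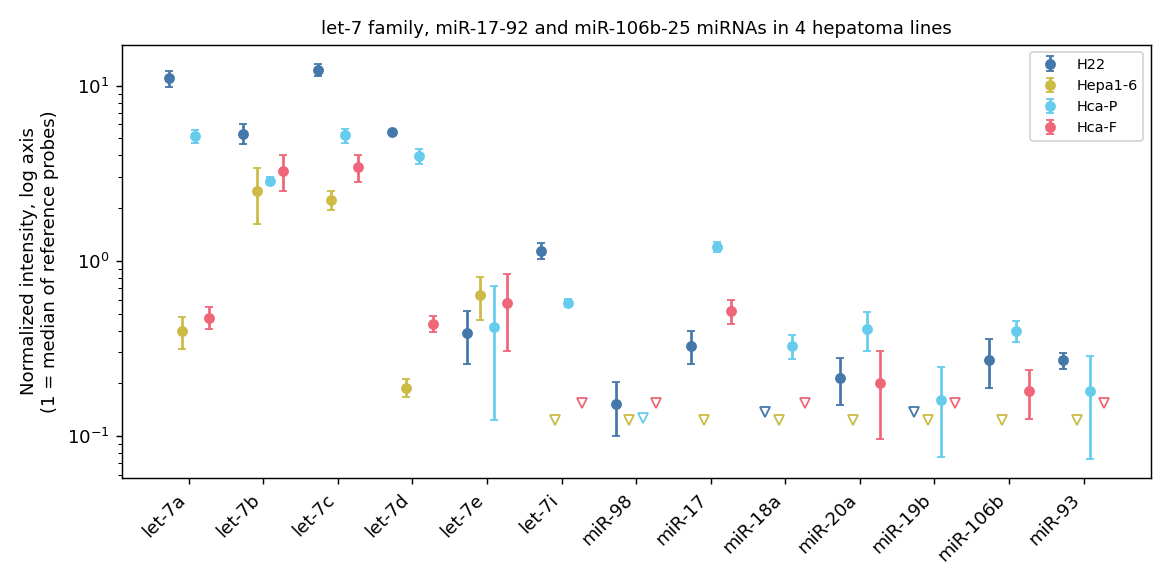
Normalized intensity (log axis, 1 = median of the reference probes of an array) of let-7, miR-17-92 and miR-106b-25 miRNAs in H22, Hepa1-6, Hca-P and Hca-F, 1 array each; points are means and bars SDs over 4 spots, and open triangles mark the detection floor of an array where a miRNA lay under it. let-7a was at 11 in H22 and 5.15 in Hca-P against 0.396 in Hepa1-6 and 0.475 in Hca-F, while let-7b lay between 2.5 and 5.33 in the 4 lines.

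Hca-P, whose lymphatic metastasis ability is lower than that of Hca-F, was compared with H22, the line it derives from, which has none. The largest lower bound was that of miR-697, which was at 4.87 ± 0.351 in H22 and under the detection minimum in Hca-P, at least 38.6-fold lower. miR-207 (1.68 ± 0.161 in H22) was at least 13.3-fold lower, miR-138 at least 6.85-fold, miR-378 at least 5.73-fold and miR-361 at least 4.42-fold. miR-762 (5.41 ± 0.794 against 0.519 ± 0.0757) was 10.4-fold higher in Hca-P. miR-17 was 3.69-fold higher (1.21 ± 0.0831 against 0.326 ± 0.0701), and 2 of 4 measured miR-17-92 members were 2-fold or more higher, with a median log2 fold of 1.09 (percentile 99.2; 0.58 to 1.58 in the alternatives), again set in part by the bound of miR-18a.

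miR-320 was at 13.0 ± 1.93 in Hca-P and 1.36 ± 2.26 in H22, 9.60-fold higher, a log2 fold of 3.26 that became 5.25 with the median of spots and had a spot-by-spot SD of 2.50. In H22 its SD exceeded its mean, since 1 spot read 4.74 and the other 3 read 0.0872 to 0.414. The probes named miR-720, known as a tRNA fragment (4.54-fold), miR-129-5p (3.75-fold), miR-705 (3.19-fold) and miR-763 (at least 5.01-fold) were also higher in Hca-P. miR-805, known as a mitochondrial RNA fragment, was at least 3.32-fold higher, miR-18a at least 2.39-fold, miR-706 at least 2.23-fold and miR-370 at least 2.19-fold, the last within 2 combined spot SDs. Among miRNAs measured in both lines, miR-693-5p (3.17-fold), miR-678 (3.17-fold), miR-667 (3.11-fold), miR-125a-5p (2.97-fold), miR-329 (2.92-fold) and miR-713 (2.82-fold) were lower in Hca-P. let-7c was 2.37-fold lower (5.19 ± 0.483 against 12.3 ± 0.943), let-7a 2.14-fold (5.15 ± 0.448 against 11 ± 1.17) and miR-183* 2.08-fold. The let-7 median of -0.90 over 7 members lay at percentile 15.0. In the Sfmbt2 cluster 4 of 5 members were lower, miR-467a* and miR-467d* by 3.0-fold, with a median of -1.23 at percentile 26.3. The 4 include miR-466d-3p (log2 -1.38), whose probe name carries a suffix that the sources used here do not explain, so it may not match the mouse sequence. miR-34a and miR-34c were both lower, with log2 folds of -1.34 and -1.03, the second a bound from 1 of 2 probes, the other being under the detection minimum in each line. In the miR-99, miR-100 and miR-125 family 2 of 4 members were lower, with a median of -0.99 at percentile 6.21 (-1.41 to -0.49 in the alternatives). That median averages miR-125b-5p and miR-99b*, both bounds under the detection minimum in Hca-P, so the detection floor sets it.

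Of 98 miRNAs, 49 were 2-fold or more apart between Hca-P and H22, 15 higher and 34 lower, and 38 by more than 2 combined spot SDs. The median over all 98 was -0.62, and the split moved to 18 and 22 after quantile normalization (median -0.24), 16 and 19 with all capture probes setting the factor (-0.32), and 23 and 16 with the 75th percentile of mouse probes (-0.12).

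Hca-F was compared with H22 in the same way, for the line with the higher metastasis ability. let-7a was 23.2-fold lower in Hca-F (0.475 ± 0.0670 against 11 ± 1.17), let-7d 12.5-fold (0.438 ± 0.0452 against 5.47 ± 0.103), let-7c 3.60-fold and let-7i at least 7.40-fold. The let-7 median over 7 members was -1.85, at percentile 0.165 (-2.43 to -1.29 in the alternatives), with 4 lower and none higher. miR-697 was 26.5-fold lower (0.184 ± 0.0603) and miR-207 7.36-fold (0.229 ± 0.0858). miR-23a was at least 6.19-fold lower, miR-138 at least 5.61-fold, miR-22 at least 4.79-fold and miR-378 at least 4.69-fold.

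In the miR-23-27-24 clusters 3 of 4 members were lower, all as bounds, with a median of -1.49 at percentile 7.16. Higher in Hca-F were miR-320 (9.65-fold against the uneven spots of H22, a log2 fold of 3.27 that became 5.35 with the median of spots), miR-762 (6.76-fold, 3.51 ± 0.193 against 0.519 ± 0.0757), miR-129-5p (3.73-fold), miR-705 (3.29-fold) and miR-720 (3.21-fold). miR-805, miR-706 and miR-763 were at least 3.56-fold, 3.33-fold and 2.24-fold higher. miR-1 had a log2 fold of 1.29, within 2 combined spot SDs. The Sfmbt2 median was -0.27 at percentile 59.4 and turned to 0.29 with the 75th percentile of mouse probes. Of 95 miRNAs, 31 were 2-fold or more apart, 14 higher and 17 lower, and 23 by more than 2 combined spot SDs. The median over all 95 was -0.09, and with the 75th percentile of mouse probes it was 0.47 and the split 31 and 13, against 11 and 24 with all capture probes setting the factor (-0.30) and 11 and 21 without scaling (-0.27).

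Both comparisons use the H22 array, which can raise their overlap. Among 92 miRNAs tested in both, 13 were higher in Hca-P and 14 in Hca-F than in H22, with 9 shared; independent lists would share 1.98. Of 34 and 17 that were lower, 12 were shared, against 6.28 for independent lists. Spot noise alone shared 0.16 and 0.03 on average in 100 simulations, but it made only 0.87 calls for Hca-P over H22, so it could share next to none and is no measure for lists of this length. No miRNA was higher in 1 line and lower in the other. The H22 array cannot be split, so part of the overlap beyond independent lists may come from it. Hca-P and Hca-F are also 1 of the pairs of arrays that shared spot deviations, and H22 lies in the other. An effect common to that pair of arrays could raise the overlap as well and cannot be told apart here.

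Over the 3 suspension lines, which the labels rank as none, lower and higher, let-7a, let-7c, let-7i, miR-22 and miR-23a were lower by 1.5-fold or more at both steps, from H22 to Hca-P and from Hca-P to Hca-F. The smaller step was 2.14-fold for let-7a, 2.11-fold for miR-22, 1.99-fold for let-7i, 1.58-fold for miR-23a (within 2 combined spot SDs) and 1.52-fold for let-7c. Hepa1-6, without lymphatic metastasis, was no higher than Hca-F in let-7a (0.396 ± 0.0807 against 0.475 ± 0.0670) and let-7c (2.23 ± 0.272 against 3.42 ± 0.609). let-7i, miR-22 and miR-23a were under the detection minimum in both. Over all 4 lines these miRNAs therefore did not follow metastasis ability. miR-760 was higher at both steps, by 1.59-fold or more (0.245 ± 0.128, 0.389 ± 0.0981 and 0.629 ± 0.163), with both steps within 2 combined spot SDs. That gives 6 graded miRNAs of 101. The order H22, Hca-F, Hca-P, which does not follow the labels' ranking, also gave 6 (miR-763, miR-689, miR-801, miR-17 and miR-762 higher, miR-207 lower), and the order Hca-P, H22, Hca-F gave 0. With the 75th percentile of mouse probes the ranked order gave 4 higher and 2 lower. None was higher, and 6 were lower with the 75th percentile of the miRNAs detected in all arrays, 5 without scaling or with all capture probes setting the factor, and 4 with normexp or a detection minimum of 100.

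The comparison the series is named for sets both lines with lymphatic metastasis against both without. miR-762 and miR-320 were higher in Hca-P and Hca-F than in both H22 and Hepa1-6, by 3.51-fold and 3.81-fold between the nearest lines. In limma their log2 differences were 2.60 ± 0.75 (SE) and 2.60 ± 0.77 (SE), each with an adjusted p of 0.0427, and they were the 2 of 103 miRNAs past the threshold. miR-697 had a limma log2 difference of -3.16 with an adjusted p of 0.0594. Without a test, 6 miRNAs were 2-fold or more higher in both lines with metastasis than in both without: miR-320, miR-762, miR-720 (gap 3.21-fold), miR-801, known as a fragment of the spliceosomal U11 RNA (3.0-fold), miR-129-5p (2.69-fold) and miR-805 (2.48-fold). The other 3 were lower: miR-207 (2.58-fold), miR-361 (at least 2.21-fold) and miR-697 (2.07-fold). The 6 higher and 3 lower became 5 and 4 after quantile normalization, 1 and 4 with the 75th percentile of the miRNAs detected in all arrays, 7 and 0 with normexp, and 5 and 0 with a detection minimum of 100.

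The other ways to pair the 4 lines gave 6 miRNAs (H22 and Hca-P against Hepa1-6 and Hca-F) and 2 (H22 and Hca-F against Hepa1-6 and Hca-P). The miRNAs apart between the metastasis classes include miR-720, miR-801 and miR-805, known as fragments of other RNAs, while the other pairings include none of these. U6 spliceosomal RNA, which is no miRNA, was read by 2 probes. The dimmer was under the detection minimum in each line (22.2 units in H22, 6.5 in Hepa1-6, 31.8 in Hca-P and 13.5 in Hca-F), and the other was at 4.60 ± 0.420 in Hca-P and 3.89 ± 0.407 in Hca-F against 1.12 ± 0.225 in H22 and 1.26 ± 0.0831 in Hepa1-6. The limma calls did not hold without H22, Hca-P or Hca-F (0 each; 3 without Hepa1-6) or with no scaling, the 75th percentile of mouse probes or all capture probes setting the factor (0 each), while after quantile normalization miR-697 alone passed, with a limma adjusted p of 0.0480. At an unadjusted limma p under 0.05 there were 6 miRNAs, where 5.15 would be by chance. This division of the lines coincides with the pairs of arrays that shared spot deviations, so the 2 cannot be told apart.

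**Figure D2:**
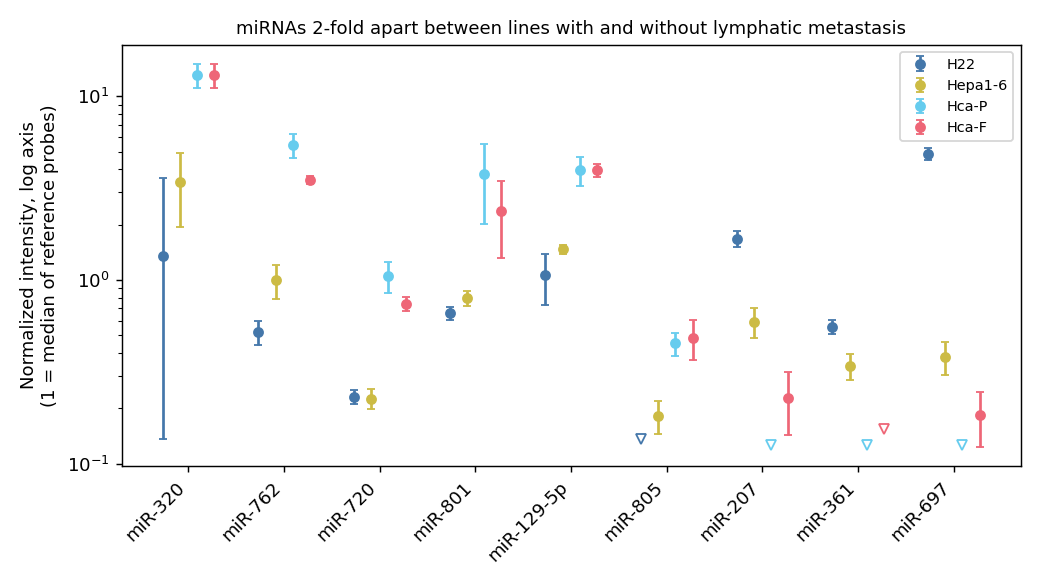
Normalized intensity (log axis, 1 = median of the reference probes of an array) of the 9 miRNAs 2-fold or more apart between both lines with lymphatic metastasis (Hca-P, Hca-F) and both without (H22, Hepa1-6); points are means and bars SDs over 4 spots of 1 array per line, open triangles mark the detection floor, and the lower bar of miR-320 in H22 is cut short because the SD of 2.26 exceeds the mean of 1.36. miR-762 was at 5.41 in Hca-P and 3.51 in Hca-F against 0.519 in H22 and 1.00 in Hepa1-6.

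H22 and Hepa1-6 both lack lymphatic metastasis and differ in origin and growth form. let-7 miRNAs were higher in H22: let-7d 28.9-fold (5.47 ± 0.103 against 0.189 ± 0.0222), let-7a 27.8-fold (11 ± 1.17 against 0.396 ± 0.0807), let-7c 5.50-fold and let-7i at least 9.20-fold. Of 7 members 5 were 2-fold or more higher and none lower, and their median log2 fold of 2.46 lay at percentile 99.9 (1.58 to 2.46 in the alternatives). miR-697 was 12.8-fold higher in H22, miR-138 5.27-fold, miR-668 4.04-fold, miR-546 3.47-fold, miR-490 3.03-fold, miR-675-5p, which is processed from the imprinted H19 transcript, 3.01-fold and miR-744 2.93-fold. miR-23a was at least 7.71-fold higher, miR-22 at least 5.96-fold, miR-378 at least 5.84-fold and miR-193 at least 4.95-fold.

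The miR-23-27-24 clusters had 4 of 4 members higher, all as bounds, with a median of 1.81 at percentile 88.5 (0.92 to 2.44 in the alternatives). miR-341 of the imprinted Dlk1-Dio3 region was at 0.462 ± 0.0505 in Hepa1-6 and under the detection minimum in H22, at least 3.39-fold lower. Of 92 miRNAs, 34 were 2-fold or more apart, 31 higher in H22 and 3 lower, and 29 by more than 2 combined spot SDs, or 31 by more than 2 SDs of the log2 fold taken spot by spot. This split also turned with the scaling: it was 14 higher and 37 lower with the 75th percentile of mouse probes and 15 and 33 with the 75th percentile of the miRNAs detected in all arrays, against 25 and 7 after quantile normalization. The median over the 92 miRNAs was 0.31 and became -0.57, -0.40 and 0.15 in turn. let-7a, let-7c and let-7d stayed higher in H22 in each alternative, by log2 folds of at least 3.92, 1.58 and 3.98.

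Between all 3 suspension lines and the adherent Hepa1-6, miR-193 was at least 3.53-fold higher in every suspension line, miR-17 at least 2.63-fold, miR-675-5p 2.62-fold or more, miR-744 2.48-fold, let-7d 2.32-fold and miR-668 2.12-fold. miR-341 was at least 3.0-fold lower. The second probe of miR-744, the dimmer, was under the detection minimum in Hepa1-6 and Hca-F, so for miR-744 the difference rests on 1 of 2 probes. These 7 miRNAs compare with 11 when H22 takes the place of Hepa1-6, 14 for Hca-P and 1 for Hca-F. With the 75th percentile of mouse probes the split was 1 higher and 8 lower, and with that of the miRNAs detected in all arrays it was 0 and 18. Hca-P against Hepa1-6 gave 28 higher and 22 lower of 89, and Hca-F against Hepa1-6 gave 22 and 8 of 81.

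**Figure D3:**
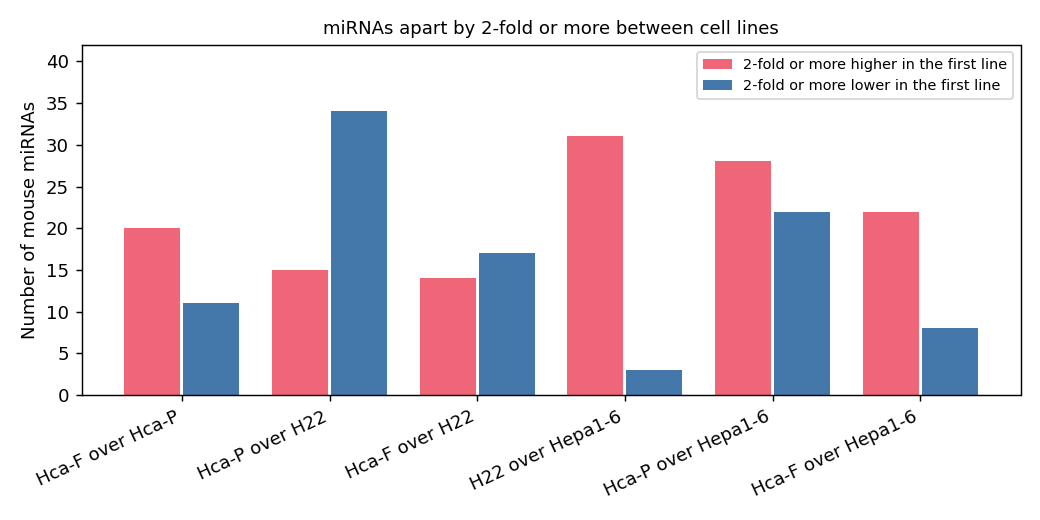
Number of mouse miRNAs 2-fold or more higher (red) or lower (blue) in the first than in the second line of each pair, under the main scaling, 1 array per line. Hca-P over H22 had 15 higher and 34 lower, and H22 over Hepa1-6 had 31 and 3.

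Markers of cell types were mostly under the detection minimum. None of 5 probes on the hepatocyte list, which includes miR-122, reached it in any line, the highest being 39.0 units in Hepa1-6. None of 3 erythroid, 2 endothelial and 4 neuronal probes did either. Of 7 leukocyte probes, miR-142-5p alone was measured, in Hca-P (0.150 ± 0.0795, with 59.2 units), and miR-223 was in no line. Of 8 mesenchymal probes, miR-214 was measured in H22, Hepa1-6 and Hca-F, at 0.192 ± 0.0551, 0.241 ± 0.0742 and 0.270 ± 0.140. The probes for the muscle miRNAs miR-1 and miR-206 reached the detection minimum in every line. miR-1 was at 2.05 ± 0.339 in H22, 2.51 ± 0.153 in Hepa1-6, 3.01 ± 1.23 in Hca-P and 5.02 ± 1.92 in Hca-F. Probes not designed for mouse also reached the minimum, 254 to 286 of 1595 per line, so signal at a probe may be nonspecific. Whether these 2 probes read the named miRNAs was not tested. miR-21, a miRNA abundant in many tumours, was measured in H22 alone, at 0.198 ± 0.0407. Of 8 probes on the miR-200 list, which marks epithelial cells, miR-200b* alone was measured, between 0.128 and 0.228 in the 4 lines.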

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

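Except for the test of the probes not designed for mouse, which was set before its result was seen, the tests in this part were chosen after the patterns had been seen. Signal was found in data that the comparisons of lines do not use. Of 1595 probes marked as not designed for mouse, 207 reached the detection minimum in all 4 arrays, as did 13 obsolete and 11 miRPlus probes, while the negative-control probes reached at most 8 units. Array by array, 286 of the 1595 reached it in H22, 277 in Hepa1-6, 254 in Hca-P and 262 in Hca-F. Of 414 mouse miRNAs, 87, 71, 75 and 74 did, a similar share. Reaching the minimum therefore does not by itself show that a probe read a mouse miRNA. Of 2 U6 probes the measured one differed by 4.11-fold between its highest and lowest line, and the SNORD3@ probe by 1.63-fold. Landmark spots that carry the Hy3 dye itself agreed within 8 intensity units in 159 of 160 spots between H22 and Hepa1-6 and in 156 of 160 between Hca-P and Hca-F, against at most 1 spot in the other 4 pairs of arrays, with median values of 12428 and 13707 units in H22 and Hca-P.

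The shared spot deviations were set against technical explanations, and no biological one was tested, since cells do not set the position of a spot. Deposition of 1 hybridization under 2 names is argued against by the 20 and 29 miRNAs that were 2-fold apart beyond 2 combined spot SDs within the pairs, where 100 simulations of spot noise alone in each of these pairs gave at most 4 that were 2-fold apart. A printing pattern common to all arrays is argued against by the gap of 0.453 (95% bootstrap interval 0.329 to 0.497) between the lowest correlation within the pairs and the highest outside them. Reading of 2 samples from 1 array or slide may account for the pattern: the lower correlation of 0.697 within the pairs and the landmark spots met the requirement set for it. That requirement was set after the pattern had been seen and uses the same correlation, so meeting it is no separate support. The landmark spots differed by a median of only 3 units between H22 and Hepa1-6 and 4 between Hca-P and Hca-F. Whether 2 samples read from 1 array or slide would agree so closely was not tested. Other causes that 2 arrays may share were not tested. The labels give the dye Hy3 for every sample and name no slide, so reading from 1 array or slide stays a hypothesis.

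If the pairs are slides, the contrast of metastasis classes runs between slides, and so do the measured U6 probe and the 9 miRNAs apart in it. Of 342 detected probes not designed for mouse, 7.89% (95% Clopper-Pearson interval 5.27 to 11.3) were 2-fold apart in the same division, close to 8.74% (4.07 to 15.9) of the mouse miRNAs, so an effect of the slides may be present and cannot be told apart from metastasis ability. Some of those probes may capture mouse miRNAs of like sequence, which keeps the question open. There are only 3 ways to pair 4 lines, too few for a share under 0.05: 1 of them, the real one, gave 9 miRNAs, and the highest other gave 6. The 9, and so the 8.74%, count miR-720, miR-801 and miR-805, known as fragments of other RNAs. Without these the real pairing would not exceed the highest other, which includes none of them.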

How the results depend on the processing

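Scaling by the 75th percentile of detected miRNAs or by all capture probes, the counts of only those miRNAs beyond 2 spot SDs, combined or spot by spot, the fit without the detection filter on log2(value + 50) and the omission of suspension lines from the growth form comparison were chosen after seeing the data. Of 132 named folds 14 turned direction in at least 1 setting run, as did 6 of 24 list medians, all under 2-fold in the main setting. Larger folds mostly exceed what the scalings move, so that they kept their direction says little. Counts did move, and the cause was not tested unless the setting itself sets it. The authors' normalized values are the main values, so that setting tests nothing.

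For Hca-F over Hca-P (31) the count was 19 after quantile normalization, 15 with normexp, 20 beyond 2 spot SDs, 17 with a minimum of 100, 125 with all capture probes, 55 at 1.5-fold and 5 at 3-fold. For Hca-P over H22 (49) it was 32 with a minimum of 100, 200 with all capture probes and 21 at 3-fold. For Hca-F over H22 (31) it was 145 with all capture probes and 50 at 1.5-fold. For H22 over Hepa1-6 (34) it was 21 with a minimum of 100, 109 with all capture probes, 59 at 1.5-fold and 19 at 3-fold.

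The 2 limma calls between metastasis classes became 1 after quantile normalization and with the 75th percentile of detected miRNAs (miR-697 in both), without the filter on log2(value + 50) (miR-138) and with the median of spots (miR-320, adjusted p 0.000683), so the miRNA called depends on the setting. They became 0 with the 75th percentile of mouse probes, all capture probes setting the factor, no scaling, a minimum of 100, normexp and no trend, where limma's unadjusted p was under 0.05 for 6 to 13 miRNAs, and 9 of 489 over all capture probes. Leaving out 1 line gave 0 to 3, the lone line of a class being assumed to vary like the other class. The planned limma fit without the filter on floored values could not be fitted.

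The 9 miRNAs apart in every line with against every line without metastasis became 5 with the 75th percentile of detected miRNAs and with a minimum of 100, 41 with all capture probes, 16 at 1.5-fold and 3 at 3-fold, and 11 to 30 without 1 line. The 6 graded miRNAs became 19 with all capture probes, 2 at 2-fold and 0 at 3-fold. The 7 apart between suspension lines and Hepa1-6 became 18 with the 75th percentile of detected miRNAs, 4 without scaling, 2 with a minimum of 100, 3 with normexp, 18 with all capture probes, 17 at 1.5-fold and 1 at 3-fold, and 10 to 24 without 1 suspension line. No paired analysis was possible because each line has 1 array. Signal over background limits what can be seen: at most 21.0% of the mouse miRNAs were measured in a line.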

Other observations

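Except for the labelling test, which was set before its result was seen, the tests in this part were chosen after the pattern had been seen. Several fixed lists had few measured members. On the list for the Dlk1-Dio3 region, an imprinted cluster, 7 of 44 probes were measured in any line. The list does not hold miR-770-3p, which was measured in every line, so it may not cover the whole region. miR-494, miR-667 and miR-668 were among the brightest on the list in H22, Hca-P and Hca-F. miR-494 was at 9.80 ± 2.37 in H22, 3.99 ± 0.222 in Hepa1-6, 5.61 ± 1.32 in Hca-P and 8.53 ± 1.90 in Hca-F. The list's median log2 fold was 0.65 for Hca-F over Hca-P (percentile 74.6), -0.93 for Hca-P over H22 (12.1), -0.33 for Hca-F over H22 (18.1) and 0.32 for H22 over Hepa1-6 (53.8). The last turned to as low as -0.56 under both 75th percentile scalings, and that for Hca-F over H22 to as high as 0.23, with the 75th percentile of mouse probes or a minimum of 30. The hypoxia miRNA miR-210 was at 0.452 ± 0.0383 in H22, 0.667 ± 0.0597 in Hepa1-6, 0.428 ± 0.0654 in Hca-P and 0.645 ± 0.0322 in Hca-F. miR-183*, of the miR-183 cluster, was at 4.15 ± 0.610 in H22 and 4.03 ± 0.164 in Hca-F against 1.90 ± 0.232 in Hepa1-6 and 1.99 ± 0.162 in Hca-P.

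Of the miR-15 and miR-16 family, miR-16 was measured in H22 (0.268 ± 0.0438) and miR-195 in H22 and Hepa1-6. Of the miR-322 cluster, miR-351 was measured in every line and miR-322 in H22 and Hepa1-6. Of miR-221 and miR-222, miR-222 was measured in Hca-P, at 0.274 ± 0.159. Of 7 probes for miRNAs reported to promote metastasis, miR-21 was measured in H22 and miR-103 in Hca-P (0.127 ± 0.105). Of 13 for miRNAs reported to restrain it, miR-31, miR-34a and miR-206 were measured, with a median log2 fold of -0.86 for Hca-P over H22 (percentile 45.5). The median was -0.61 for H22 over Hepa1-6 (5.1) and 1.02 for Hca-F over Hca-P, where 2 members were measured. For Hca-F over H22 it was 0.11 (68.6) and changed sign in 7 of 11 alternatives. The miR-29, miR-30, miR-10 and miR-181 families and the miR-290-295 and miR-302-367 clusters of embryonic stem cells had no member at the detection minimum in any line.

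One division of the lines did not follow metastasis ability. let-7a (gap 10.9-fold), let-7d (9.03-fold), miR-23a (at least 3.92-fold), let-7i (at least 3.71-fold), miR-22 (at least 2.27-fold) and miR-130a (2.20-fold) were higher in H22 and Hca-P than in Hepa1-6 and Hca-F, and none was lower. A signal added alike to every probe of an array is argued against by the spike-control probes, which were not chosen for the pattern: the highest in H22 and Hca-P was at 19.8 intensity units before scaling, and the smallest gap over the 6 miRNAs, 112 units, would need as much. A nonspecific signal that differs from probe to probe was not tested. A labelling or dye difference between the members of each pair of arrays may still account for it. Of 342 detected probes not designed for mouse, 6 (1.75%) were apart in this division, 6 higher and 0 lower in H22 and Hca-P. The mouse miRNAs apart in it were 6 of 103. The other divisions gave 27 and 1 probes not designed for mouse. The median spike-control probe was also higher in H22 (8.38 units) and Hca-P (8.75) than in Hepa1-6 (1) and Hca-F (2.75). Not all of the let-7 family followed the division. let-7b and let-7c had log2 folds of 0.18 and -0.60 for Hca-F over Hca-P, and let-7e ran the other way, at 0.388 ± 0.129 in H22 and 0.420 ± 0.297 in Hca-P against 0.637 ± 0.175 in Hepa1-6 and 0.572 ± 0.268 in Hca-F.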
